A study of Arabidopsis thaliana with 6 samples.

How the data were processed

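Transcript levels were measured on 6 Affymetrix ATH1 arrays of Arabidopsis thaliana, accession Col-0, with 1 RNA sample per array. Per the labels, 3 arrays held G2/M cells, taken by fluorescence-activated cell sorting (FACS) from roots that carried a CYCB1;1-GFP reporter. The other 3 held whole root meristems dissected under a microscope. CYCB1;1 is a B-type cyclin that accumulates around mitosis, so the reporter marks dividing cells. Per the labels' protocols, total RNA was extracted with a commercial isolation kit and biotin-labelled cRNA was made by the standard Affymetrix procedure. The series names the 3 samples of each group as biological replicates, and the p-values measure the spread between these samples.

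The deposited table holds log2 values, 1 per probe set and array. Per the submitters' processing notes the arrays were processed with GCRMA, which corrects background from probe sequence, normalizes across arrays and summarises probes to probe sets; its version was not given in the sources used here. The authors' log2 values lay between 2.27 and 14.2, and 28.2% of the tested values stood at the lowest value, called the floor here. The 6 arrays had near-identical distributions, with medians between 3.61 and 3.79. A difference that starts within 0.5 of the floor is a difference from a background level, and no fold is given for it. Arrays have no read depth; their number, 3 per group, limits the precision.

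The table held 22810 probe sets. The 64 Affymetrix control probe sets were kept out of the tests, which left 22746. The platform annotation named 1 gene for 13513 of the tested probe sets and several genes for 503, which were given no name; 8730 were unnamed here. Of the probe sets with 1 gene, 13436 were matched by gene identifier to the RefSeq gene table of assembly TAIR10.1, used for names only, and 77 kept the platform's name. No genome build is named by the files, so no coordinates are given. For a gene with several probe sets, the one with the highest mean over the 6 arrays stood for it. Among 147 such genes, the probe sets of 14 disagreed on the call, AT1G79150 among the named ones, and none had called probe sets of opposite sign.

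The groups were compared with limma version 3.58.1 in R version 4.3.3 (lmFit, then eBayes with neither trend nor robust prior) on the deposited values, with no filter and no further normalization. P-values were adjusted by the Benjamini-Hochberg method over all 22746 probe sets, and a call is an adjusted p under 0.05. Every adjusted p for a gene below comes from this limma fit unless another setting is named. All differences are sorted G2/M cells minus root meristem on the log2 scale, with the moderated standard error of the fit (SE). The prior of the fit had 0.391 degrees of freedom, beside 4 residual degrees of freedom per probe set, so the moderation was slight.

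Gene lists were written from general knowledge before the data were examined: 23 lists with 383 entries. Of these entries 54 had a probe set of their own name, and 5 lists had no measured member and were not analysed here; 11 entries were left out because their locus carried another symbol. A further 14 lists were written after the table of probe names and the control probe sets had been seen, but before any difference between the groups was computed. They cover kinesins, further G2/M genes, cytosolic ribosomal proteins, ribosome biogenesis, further heat shock genes, rapid stress genes, root hair genes, further replication genes, subunits of the anaphase-promoting complex, augmin and gamma-tubulin, tubulins, expansins and xyloglucan endotransglucosylases, class III peroxidases, and plastid-encoded genes. Several lists share members: phragmoplast motors are also kinesins, and the shorter heat shock and replication lists lie within the longer ones. The 18 lists with at least 4 measured genes were tested with limma's camera (preset correlation of 0.01), beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the 18. Smaller lists are given as counts.

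The genes named in the text follow a rule fixed with the design. It takes the 6 largest rises and 6 largest falls among calls whose groups do not overlap, whose higher group mean is above the median of all values (3.71), and whose probe set names 1 gene with a symbol. From each list it takes up to 4 called members with the largest change, or the 2 with the smallest p where none was called. It also takes every member of the lists of mitotic cyclins and kinases, CDK inhibitors and growth-regulating factors, and SCL28, MYB3R1 and MYB3R4 whatever their values. For the largest changes, a symbol was taken to mean a name other than a locus code in RefSeq or the platform annotation. Genes whose symbol comes from the gene lists alone, such as PEP and HSP17.6C, were not ranked there. The rule puts CYCB1;1 first. CYCB1;1, MYB3R1 and MYB3R4, like the lists of mitotic cyclins and of growth-regulating factors, are unnamed here and not analysed here, so the sorted reporter's own transcript could not serve as a check of the labels.

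RNA quality was read from the Arabidopsis control probe sets as the 3 prime minus 5 prime level of actin, GAPDH and ubiquitin transcripts, with an exact two-sided permutation test over the arrays; 3 arrays against 3 cannot give a p below 0.1. Poly-A spike-ins are bacterial transcripts added to an RNA sample before labelling. An array was taken to hold them where their mean level exceeded that of the absent control probe sets by over 2 log2. By this rule sorted replicate 1 and all 3 meristems held them, and sorted replicates 2 and 3 did not. The split is thus not the same as the groups but is partly tied to them.

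Both groups carry replicate numbers 1 to 3. Over the 11503 probe sets with a mean above the median, the deviations of same-numbered arrays from their group means correlated with r = 0.122, 0.249 and 0.106 for replicates 1, 2 and 3, across probe sets, and each array correlated best with its own number. Over all 22746 probe sets r was 0.0959, 0.195 and 0.0742. The labels give no shared origin for a number. On the first set every correlation was above 0.1, so a pairing by these numbers was taken as possible. The planned fit has no block, so the main calls ignore such a pairing. Values with the replicate number as a block are given for the named genes and lists where they change a call.

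The alternatives were another variance prior, 2 filters on dim probe sets, 3 other scalings, array weights, the replicate block, a floor at the median of all values, each array left out in turn, other thresholds and tests, another choice of probe set per gene and other set tests. The spike-in split as a block was added after the data were seen. Its difference between the groups is that of sorted replicate 1 alone against the meristems, and whether the split marks separate preparations was not tested. The fit was tested on simulated data of 22746 probe sets with the real means and residual spreads and 200 changed probe sets. Of the 100 changed by 1 log2, 31.0% were recovered, and of the 100 changed by 2 log2, 73.0%; 7.14% of the calls were not among the changed ones. Of 20 simulated lists with 20 members each, camera called all 5 that were shifted by 1 log2 and 0 of the others. The simulated probe sets varied independently, while the estimated correlation within the real list of mitotic regulators was 0.923. The simulation therefore does not test camera on lists whose members vary together. It also gave both groups the same spread and changed only probe sets above the median. The real spread was 0.44 log2 in the sorted cells and 0.19 log2 in the meristems. The shares recovered and falsely called therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.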

Results

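Transcript profiles of sorted Arabidopsis root cells in the G2/M phase (3 arrays) were compared with profiles of complete root meristems (3 arrays). The series set out to describe the transcriptome of plant cells at this stage of the cell cycle. The meristem is the dividing region of the root tip and holds cells of every cycle phase and of every tissue layer. The groups differed in handling as well as in cells. The sorted group went through cell sorting and the other through dissection, so the difference between them covers both.

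Correlations between arrays (Pearson's r across the 22746 probe sets) lay between 0.996 and 0.997 within the meristems, between 0.967 and 0.989 within the sorted cells and between 0.952 and 0.966 across the groups. The first principal component held 70.3% of the variance and separated the groups. The second held 22.4% and separated sorted replicate 1 (score 50.7) from sorted replicate 2 (score -50.6), with sorted replicate 3 (score -0.9987) and all 3 meristems between them. Over the 11503 probe sets above the median level, the spread between replicates was 0.44 log2 in the sorted cells and 0.19 log2 in the meristems (root mean square SD, n = 3 each). The fit takes 1 spread per probe set for both groups. Where the spread lies mainly in the sorted cells, as for GRX480 (SD 1.14 against 0.01), its p-values may be too small.

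**Figure D1:**
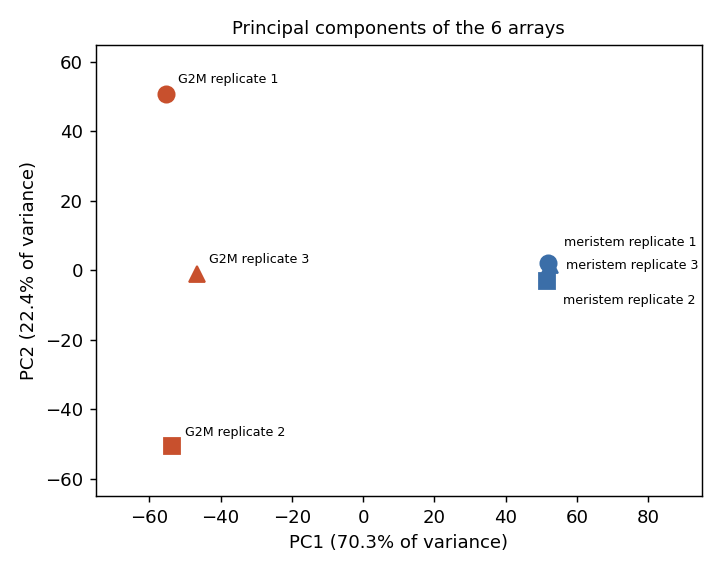
Scores of the 6 arrays on the first principal component (horizontal, 70.3% of variance) and the second (vertical, 22.4%), computed from 22746 probe sets; color marks the group and marker shape the replicate. The sorted cells (G2M) lie at negative and the meristems at positive scores on the first component, and the sorted replicates spread along the second.

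Of the measured genes, 6 of 8 mitotic regulators, 4 of 7 spindle and phragmoplast genes, 7 of 9 heat shock genes and 8 of 22 rapid stress genes rose in the sorted cells. All 4 histone H2B genes and 3 of 7 replication genes fell. Camera called each of these lists as a set with the preset correlation and none with an estimated one (adjusted p between 0.0512 and 0.200). In all, 2614 of 22746 probe sets (11.5%) were called, 1009 higher and 1605 lower in the sorted cells, so 38.6% of the calls were higher; 575 of the higher and 745 of the lower ones differed by at least 2-fold. Probe sets with 1 named gene made up 1363 of the calls, 536 higher and 827 lower. The groups did not overlap for 6983 probe sets, 30.7% of those tested, against 10% by chance. The number of calls depended on the fit. It was 235 with the replicate number as a block (79 higher, 156 lower) and 1249 with a trended robust prior. It was 1168, 1023, 959 and 1161 without sorted replicate 3 and without meristem replicates 1, 2 and 3. Without sorted replicate 1 the calls were 1752 higher and 1631 lower. Centring each array on 4 reference genes moved the median difference of the 11503 expressed probe sets from 0.02 to 0.21 log2 and the split to 12986 higher (87.0%) and 1941 lower.

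Of 8 measured mitotic regulators, 6 rose and 2 were not called (adjusted over the list alone, 7 rose). The spindle checkpoint protein BUBR1 had a level of 7.23 ± 0.53 in the sorted cells and 4.50 ± 0.17 in the meristems (SD, n = 3 each), a difference of 2.73 (SE 0.31, adjusted p = 0.0126) or 6.63-fold. The Aurora kinases, which act on chromosome alignment and division plane, rose together: AUR2 by 2.47 (SE 0.19, adjusted p = 0.00594), AUR1 by 2.09 (SE 0.20, adjusted p = 0.00851) and AUR3 by 1.90 (SE 0.27, adjusted p = 0.0226). SCL28, a GRAS-family transcription factor of the cell cycle, rose by 1.86 (SE 0.11, adjusted p = 0.00338), from 6.64 ± 0.06 to 8.50 ± 0.18 (SD, n = 3 each). The list as a set was higher (camera adjusted p = 7.62e-07), with an adjusted p of 0.200 with an estimated correlation and 1.89e-05 with the replicate block. With that block 0 of the 8 genes were called, and SCL28 had an adjusted p of 0.0539. BUBR1 and AUR3 lost their calls, and the count was 3 of 8, when sorted replicate 3 or any 1 of the meristem arrays was left out.

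Several motor proteins of the spindle and of the phragmoplast, the structure that builds the new cell wall, also rose. Of 7 genes in this list 4 rose and 3 were not called (adjusted over the list alone, 4 rose and 1 fell). PAKRP2, a phragmoplast kinesin, rose 6.36-fold (2.67 log2, SE 0.18, adjusted p = 0.00466), KINESIN-12B rose 5.75-fold (2.52 log2, SE 0.20, adjusted p = 0.00620) and KRP125C, a bipolar spindle kinesin, rose 5.35-fold (2.42 log2, SE 0.11, adjusted p = 0.00274). KRP125B rose by 1.20 log2 (SE 0.18, adjusted p = 0.0255) and lost its call without sorted replicate 3 or any 1 of the meristems. Among 28 kinesins 13 rose, 1 fell and 14 were not called (adjusted over the list alone, 14 rose and 4 fell), with AT3G10310 (2.72 log2) and AT2G22610 (2.55 log2) among the largest rises. The set tests gave adjusted p = 0.00400 for the spindle list and 1.21e-05 for the kinesins, and 0.181 for both with an estimated correlation. The spindle list also lost its set call when the arrays were centred on the reference genes (adjusted p = 0.106). With the replicate block 0 genes of either list were called, while the set tests gave adjusted p = 0.0239 and 5.37e-04.

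Among 10 further genes known to peak around mitosis, 9 rose and 1 was not called (adjusted over the list alone, 10 rose). AT3G51280 rose by 2.80 log2 (SE 0.16, adjusted p = 0.00328), AT4G26660 by 2.77 (SE 0.16, adjusted p = 0.00328), AT4G02800 by 2.66 (SE 0.13, adjusted p = 0.00280) and 3xHMG-box1, which binds condensed chromosomes, by 2.57 (SE 0.22, adjusted p = 0.00742). The set test gave adjusted p = 1.78e-12 (0.181 with an estimated correlation), and 1 of the 10, AT4G26660, was called with the replicate block. Of 4 genes of chromosome structure and kinetochores 2 rose (adjusted over the list alone, 3): DNA topoisomerase TOPII by 2.09 (SE 0.12, adjusted p = 0.00357) and the condensin subunit CAP-D2 by 1.60 (SE 0.22, adjusted p = 0.0202). The set test of that list gave adjusted p = 0.0167, with 0.359 under an estimated correlation, 0.0716 with the spike-in block, 0.198 with centring on the reference genes and 0.0524 with centring on expressed probe sets. None of the 4 was called with the replicate block. CAP-D2 was not called with the spike-in block, without sorted replicate 3 or without any 1 of the meristems. The anaphase-promoting complex genes HBT (0.32 log2, adjusted p = 0.331) and CDC27a (-0.10 log2, adjusted p = 0.585) were not called.

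In each sorted array these lists lay above the meristem mean. The median over the mitotic regulators was 1.53, 2.16 and 1.96 log2 above it in sorted replicates 1, 2 and 3, over the further G2/M genes 2.15, 2.65 and 2.47, and over the kinesins 0.40, 0.82 and 0.60. Sorted replicate 1 and the meristems carried poly-A spike-ins and sorted replicates 2 and 3 did not, so the value for replicate 1 is also the difference between arrays that carried them. With this split as a block, chosen after the data were seen and resting on 1 sorted array, 7 of the 8 mitotic regulators, 5 of the 7 spindle genes, 15 of the 28 kinesins and 9 of the 10 further G2/M genes were higher.

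Histone H2B genes and some genes of DNA replication fell. All 4 measured H2B genes fell (4 adjusted over the list alone): HTB2 (-2.23 log2, SE 0.18, adjusted p = 0.00631), HTB11 (-1.503 log2, SE 0.09, adjusted p = 0.00382), HTB1 (-1.23 log2, SE 0.08, adjusted p = 0.00385) and HTB4 (-1.11 log2, SE 0.02, adjusted p = 6.25e-04). HTB4 went from 11.72 ± 0.02 in the meristems to 10.62 ± 0.04 in the sorted cells (SD, n = 3 each) and was the 1 H2B gene called with the replicate block (adjusted p = 0.0263). The set test gave adjusted p = 3.75e-07, and 0.0512 with an estimated correlation. Of 3 genes planned for replication 2 fell (2 adjusted over the list alone): ICU2, the catalytic subunit of DNA polymerase alpha (-1.52 log2, SE 0.11, adjusted p = 0.00546), and PRL, a subunit of the MCM helicase (-1.40 log2, SE 0.08, adjusted p = 0.00352). In the longer list 3 of 7 fell (4 adjusted over the list alone), among them the primase subunit POLA3 (-1.55 log2, SE 0.24, adjusted p = 0.0267). The set test gave adjusted p = 2.70e-04, or 0.200 with an estimated correlation. With the replicate block 0 of the 7 were called, and POLA3 also lost its call without sorted replicate 3 or any 1 of the meristems. The median over the H2B genes was 1.36, 1.38 and 1.36 log2 below the meristem mean in the 3 sorted arrays (median differences of -1.36, -1.38 and -1.36).

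**Figure D2:**
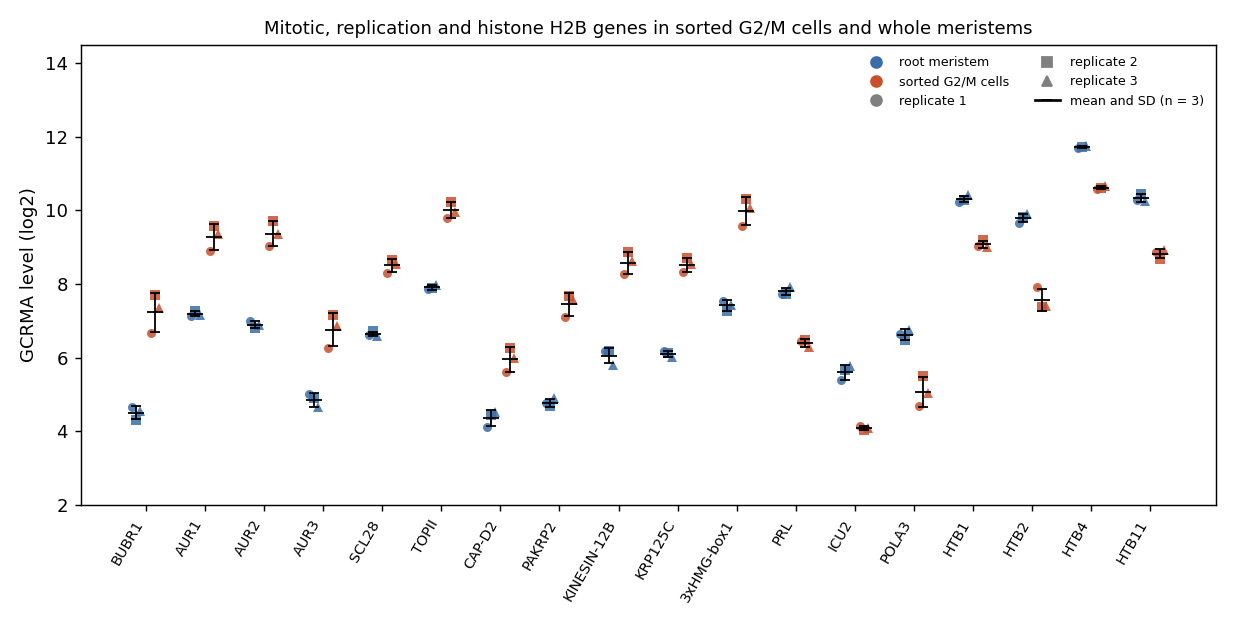
GCRMA level (log2, vertical) of genes of mitosis, replication and histone H2B (horizontal) in root meristems and sorted G2/M cells; points are arrays with the shape giving the replicate, and black bars are the mean and SD (n = 3). The mitotic genes, such as BUBR1 (7.23 against 4.50), lie higher in the sorted cells, and the H2B genes, such as HTB4 (10.62 against 11.72), lie lower.

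The tubulins, subunits of microtubules, moved apart. Of 7 genes 1 rose and 3 fell (1 and 3 adjusted over the list alone): TUB7 rose by 1.08 log2 (SE 0.20, adjusted p = 0.0411), while TUB5 fell by 2.51 log2 (SE 0.50, adjusted p = 0.04996). TUB6 (-1.28 log2, SE 0.11, adjusted p = 0.00679) and TUB9 (-0.76 log2, SE 0.09, adjusted p = 0.0149) also fell. The set as a whole was lower (camera adjusted p = 0.0108, 0.181 with an estimated correlation and 0.103 with the spike-in block). TUB5 and TUB7 lost their calls with the trended prior, the replicate block, the spike-in block and with any 1 array left out, except sorted replicate 2 for TUB5 and sorted replicate 1 for TUB7. TUB6 lost its call with the replicate block (adjusted p = 0.0726). TUB9 kept its call with that block (adjusted p = 0.0273) but not without sorted replicate 2 or meristem replicate 2 or 3. Of 2 genes of augmin and gamma-tubulin complexes, AT3G43610 fell by 0.42 log2 (SE 0.07, adjusted p = 0.0277; 0.151 with the replicate block) and 1 was not called; AT3G43610 also lost its call with the trended prior (adjusted p = 0.206) and without sorted replicate 3 or any 1 meristem array.

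The 6 genes with a symbol that rose most under the naming rule were picked by size, not as members of a list. HSP17.6C, with a symbol from the gene lists alone, was not ranked but rose by more than CML37. STZ, a zinc finger repressor of abiotic stress responses, stood at 7.76 ± 0.07 in the sorted cells and near the floor in the meristems (2.40 ± 0.19, SD, n = 3 each), a difference of 5.36 (SE 0.11, adjusted p = 6.25e-04). The calmodulin-like genes CML38 and CML37 rose by 5.14 (SE 0.18, adjusted p = 0.00171) and 3.33 log2 (SE 0.21, adjusted p = 0.00417), the second from near the floor. GRX480, a glutaredoxin, rose by 4.73 (SE 0.63, adjusted p = 0.0187), ZCF37 by 4.13 (SE 0.50, adjusted p = 0.0154) and ORA47, an AP2/ERF transcription factor, by 4.03 (SE 0.22, adjusted p = 0.00319). With the replicate block STZ (adjusted p = 0.0263) and CML38 (0.0434) were called and GRX480 (0.104), ZCF37 (0.0930), ORA47 (0.0570) and CML37 (0.0570) were not. GRX480 and ZCF37 also lost their calls without sorted replicate 3 or without any 1 of the meristem arrays.

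Of 22 rapid stress genes 8 rose and 14 were not called (11 rose, adjusted over the list alone), among them AT4G29780 (5.32 log2, SE 0.17, adjusted p = 0.00153), AT1G19020 (4.16 log2, SE 0.38, adjusted p = 0.00799) and AT1G05575 (3.16 log2, SE 0.25, adjusted p = 0.00594), all from near the floor. Of 9 heat shock genes 7 rose (8 adjusted over the list alone): HSP17.6C by 3.91 (SE 0.19, adjusted p = 0.00274), AT5G51440 by 3.48 (SE 0.27, adjusted p = 0.00591), AT1G54050 by 3.25 (SE 0.17, adjusted p = 0.00318) and AT2G29500 by 3.197 (SE 0.31, adjusted p = 0.00890; not called without meristem replicate 2). Of the 2 planned heat shock genes 1 rose (1 adjusted over the list alone), HSP17.6C. The set tests gave adjusted p = 2.81e-07 for the rapid stress genes and 9.49e-10 for the heat shock genes, with 0.181 and 0.0512 under an estimated correlation. With the replicate block 2 of the 22 and 2 of the 9 were called, and 5 of the 22 without sorted replicate 3 or without meristem replicate 3. Of 5 wound, jasmonate and defence genes 1 rose (2 adjusted over the list alone), STZ; the set test gave adjusted p = 0.0167, 0.200 with an estimated correlation, 0.168 with centring on the reference genes and 0.133 without sorted replicate 1. The median over the heat shock genes was 2.78, 2.98 and 2.90 log2 above the meristem mean in sorted replicates 1, 2 and 3, and over the rapid stress genes 1.26, 0.71 and 0.80.

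The 6 genes with a symbol that fell most under the naming rule were picked in the same way. PEP, with a symbol from the gene lists alone, was not ranked but fell by more than MSRB5 and sks15. XTH16, a xyloglucan endotransglucosylase, stood at 7.96 ± 0.21 in the meristems and near the floor in the sorted cells (2.54 ± 0.04, SD, n = 3 each), a fall by 5.43 log2 (SE 0.12, adjusted p = 6.25e-04). The class III peroxidase Prx37 fell by 5.36 (SE 0.11, adjusted p = 6.25e-04), or 41.0-fold, as did the subtilase SBT4.12 (-5.13 log2, SE 0.38, adjusted p = 0.00529) and the multicopper oxidase-like genes sks16 (-4.94 log2, SE 0.36, adjusted p = 0.00512) and sks15 (-3.73 log2, SE 0.17, adjusted p = 0.00268). MSRB5, a methionine sulfoxide reductase, fell by 3.80 (SE 0.64, adjusted p = 0.0327) and lost its call without sorted replicate 3, without any 1 of the meristems and with the spike-in block (adjusted p = 0.115). With the replicate block XTH16 (0.0383), Prx37 (0.0340) and SBT4.12 (0.0340) were called, and sks16 (0.0846), sks15 (0.0602) and MSRB5 (0.131) were not. Among 29 expansin and xyloglucan endotransglucosylase genes 3 fell and 26 were not called (3 fell, adjusted over the list alone), XTH16, EXPA15 (-2.37 log2, SE 0.28, adjusted p = 0.0147) and EXGT-A3 (-1.32 log2, SE 0.22, adjusted p = 0.0322). Of the 6 genes in the class III peroxidase list 1, Prx37, fell (1 adjusted over the list alone). This list does not hold every peroxidase gene measured. Camera called neither the wall list (adjusted p = 0.243) nor the peroxidases (0.433), while fry called both (adjusted p = 0.0127 and 0.00116). With an estimated correlation camera gave adjusted p = 0.524 and 0.560. Camera called the wall list with the filter at the median (0.0429) and with centring on the reference genes (0.0290). Under that centring, which adds the same shift to every gene, 13 wall genes were called higher and 4 lower. In the peroxidase list 4 were called higher and 1 lower. On all arrays 5 of the wall genes and 3 of the listed peroxidases stood at the floor, and for these any difference is the shift itself. EXPA15 lost its call with the replicate block (adjusted p = 0.104), without sorted replicate 3 and without any 1 of the meristems. EXGT-A3 lost its call with the replicate block (adjusted p = 0.0682), with the spike-in block, with the trended prior and without any 1 of the 6 arrays.

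Of 11 measured genes in the lists of stem cell niche, root cap, epidermis, cortex, phloem and pericycle, 4 fell and 7 were not called. The cortex marker PEP fell by 4.52 log2, from 7.54 ± 0.39 to 3.02 ± 0.45 (SD, n = 3 each; SE 0.33, adjusted p = 0.00512; 0.0263 with the replicate block), and so did CO2, also of the cortex (-0.79 log2, SE 0.11, adjusted p = 0.0191), so 2 of 2 cortex genes fell (2 adjusted over the list alone). CO2 lost its call with the trended prior (adjusted p = 0.0860), the replicate block (0.129) and the spike-in block (0.0781). RCPG, a polygalacturonase of the root cap, fell by 3.23 (SE 0.51, adjusted p = 0.0280; 0.0877 with the replicate block and 0.0632 with the spike-in block). Of 3 stem cell niche genes 1 fell (1 adjusted over the list alone), JKD, a ground tissue zinc finger protein (-2.29 log2, SE 0.19, adjusted p = 0.00687; 0.0881 with the replicate block). The cytokinin response regulator ARR15 fell by 1.31 to near the floor (SE 0.10, adjusted p = 0.00549; 0.0669 with the replicate block), and lost its call with values floored at the median. The phloem gene OPS (0.51 log2, adjusted p = 0.324), the lateral root genes LBD16 (0.05 log2, adjusted p = 0.456) and LBD29 (at the floor on all arrays) and the photosynthesis gene LHCB4.1 (-0.51 log2, adjusted p = 0.247) were near the floor in at least 1 group and not called; OPS was called without sorted replicate 1 (adjusted p = 0.0212). RCPG and CO2 were not called without sorted replicate 2 or 3 or without meristem replicate 1 or 3, and RCPG also not without meristem replicate 2.

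Of the inhibitors of cyclin-dependent kinases that promote endoreplication, SIM stood at 5.42 ± 1.45 in the sorted cells and 8.14 ± 0.18 in the meristems (SD, n = 3 each), a difference of -2.72 (SE 0.81) that was not called (adjusted p = 0.124). SMR2 was near the floor in both groups (2.70 and 2.73, adjusted p = 1). Neither gene was called, while SIM fell when the p-values were adjusted over the list alone. SIM was called in 4 settings: without sorted replicate 2 (-1.90 log2, adjusted p = 0.0453), with the filter at the median, with centring on the reference genes and with array weights. Its difference was -1.57 with the spike-in block. Its levels in sorted replicates 1, 2 and 3 were 6.57, 3.79 and 5.91.

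Root hair genes, which belong to differentiated epidermal cells, were high in 1 sorted array. EXPA7 stood at 7.07 in sorted replicate 1, 2.42 in replicate 2 and 2.69 in replicate 3, and between 2.27 and 2.29 in the meristems. EXPA18 stood at 6.67, 2.31 and 2.35 in sorted replicates 1, 2 and 3, AT3G49960 at 6.24, 2.27 and 2.78, and HRGP1 at 6.96, 3.19 and 4.65. The differences between the groups, 1.78 for EXPA7 (SE 1.44, adjusted p = 0.595), 1.497 for EXPA18 (SE 1.38, adjusted p = 0.613), 1.49 for AT3G49960 (adjusted p = 0.588) and 1.63 for HRGP1 (adjusted p = 0.466), were within the spread of the sorted arrays. None of the 7 genes of the list, nor of the 2 planned epidermal genes, EXPA7 and EXPA18, was called (set test of the 7 genes, adjusted p = 0.125, and 0.0159 without sorted replicate 2). Without sorted replicate 1 the differences were 0.28 for EXPA7, 0.05 for EXPA18, 0.26 for AT3G49960 and 0.62 for HRGP1. The spike-in block compares sorted replicate 1 alone with the meristems and is no separate test of these genes.

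**Figure D3:**
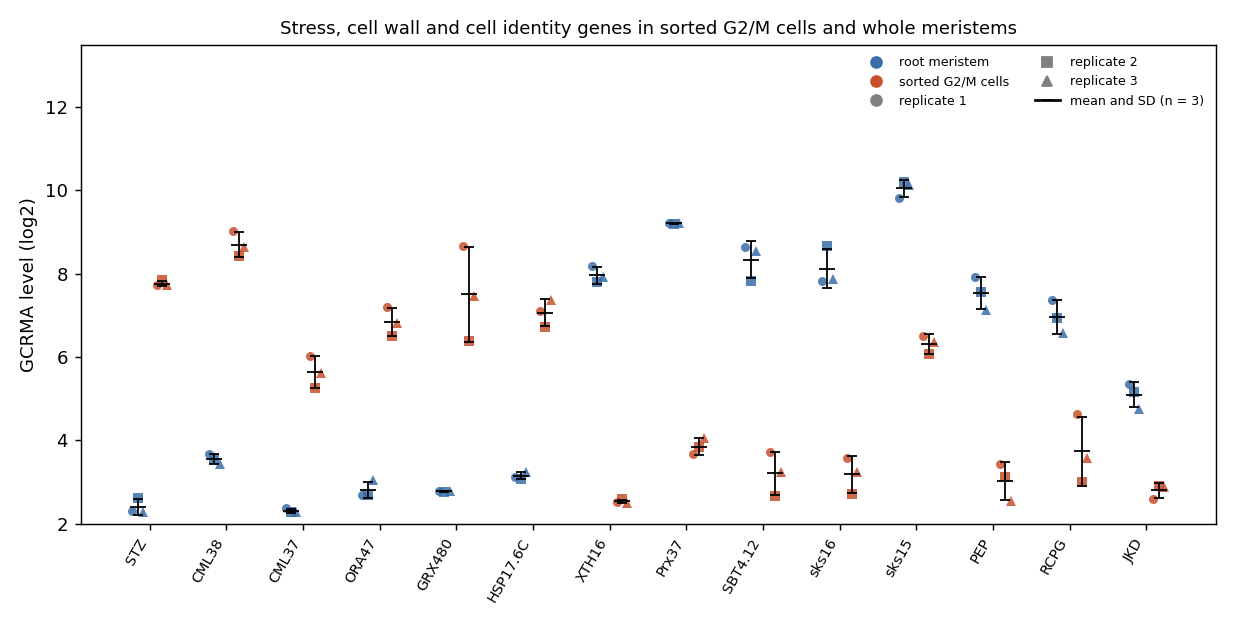
GCRMA level (log2, vertical) of stress, cell wall and tissue marker genes (horizontal) in root meristems and sorted G2/M cells; points are arrays with the shape giving the replicate, and black bars are the mean and SD (n = 3). STZ lies at 7.76 in the sorted cells against 2.40 in the meristems, and XTH16 at 2.54 against 7.96.

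Ribosome genes differed by small amounts, with the biogenesis genes all higher in the sorted cells. Of 22 ribosome biogenesis genes 7 rose and 15 were not called (19 rose, adjusted over the list alone). All 22 differences lay between 0.40 and 0.75 log2. AT2G18220 (0.75 log2, SE 0.14, adjusted p = 0.0440), AT1G79150 (0.69 log2, SE 0.11, adjusted p = 0.0292), AT5G14520 (0.66 log2, SE 0.09, adjusted p = 0.0199) and PRH75 (0.62 log2, SE 0.09, adjusted p = 0.0206) had the largest called differences. The set test gave adjusted p = 1.96e-10, with 0.218 under an estimated correlation and 0.00982 with fry. The number called was 22 with centring on the reference genes or array weights, 18 and 12 with the filters at the median and the lower quartile, 11 with centring on expressed probe sets, 3 with the trended prior and 2 with the spike-in block. It was 17 without sorted replicate 1, 2 without sorted replicate 2, 0 without sorted replicate 3 or meristem replicate 1 or 3, 1 without meristem replicate 2, and 0 with the replicate block. Of 110 cytosolic ribosomal protein genes 4 rose and 106 were not called (0 adjusted over the list alone), with a median difference of 0.08 log2 (0.04 without sorted replicate 2); the set test gave adjusted p = 8.80e-06, but 0.463 with an estimated correlation, 0.144 with fry and 0.374 with the spike-in block. AT5G59240 rose by 1.07 log2 (SE 0.15, adjusted p = 0.0222), and AT3G04920, AT1G08360 and AT5G27700 by 0.18, 0.17 and 0.09, and each of the 4 lost its call with the replicate block and with the spike-in block, and the last 3 also with the trended prior (adjusted p = 0.197, 0.157 and 0.410). The last 3 lost their calls with the filter at the median too. AT5G59240 also lost its call without sorted replicate 3 or any 1 of the meristems. The number higher in this list was 90 with centring on the reference genes, 55 with array weights (3 lower), 11 with centring on expressed probe sets, 8 with quantile normalization (3 lower), 7 and 2 with the filters at the lower quartile and the median, 3 with values floored at the median, 2 with the spike-in block (2 lower) and 1 with the trended prior. It was 13 without sorted replicate 1, 1 without sorted replicate 2 or meristem replicate 3, 3 without sorted replicate 3, and 0 without meristem replicate 1 or 2. The 2 planned ribosomal genes, RPL28A (-0.03 log2, adjusted p = 0.792) and RPL4A (0.02 log2, adjusted p = 0.827), were not called.

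Of 69 plastid-encoded genes 3 fell and 66 were not called (0 adjusted over the list alone): ndhC (-1.42 log2, SE 0.18, adjusted p = 0.0173), ccsA (-0.94 log2, SE 0.18, adjusted p = 0.0440) and ndhA (-0.33 log2, SE 0.05, adjusted p = 0.0296), all 3 not called with the replicate block. Of these, ndhC also lost its call without sorted replicate 3 or meristem replicate 1 or 2, ndhA without any 1 array except sorted replicate 2, and ccsA without any 1 of the 6 arrays. Both ccsA and ndhA lost their calls with the trended prior (adjusted p = 0.0804 and 0.294) and the spike-in block (0.139 and 0.0556), ccsA with values floored at the median and ndhA with centring on the reference genes. That centring gave 6 higher and 5 lower, array weights 19 lower, and the trended prior 1 lower. The median of the list was -0.16 log2, but 0.03 when the arrays were centred on the reference genes, -0.05 without meristem replicate 1 and -0.34 without meristem replicate 3. Relative to the meristem mean it was -0.17, -0.14 and -0.25 in sorted replicates 1, 2 and 3 and 0.28, -0.02 and -0.25 in the meristems, so the list did not separate the groups. The set test gave adjusted p = 4.32e-04, 0.526 with an estimated correlation, 0.292 with fry and 0.148 without meristem replicate 1. Of the 4 reference genes, commonly taken as stable, 1 fell (3 adjusted over the list alone), PEX4 (-0.54 log2, SE 0.08, adjusted p = 0.0220; 0.0942 with the trended prior, 0.0990 with the replicate block, 0.0635 with the spike-in block). PEX4 kept its call with 1 array left out only where that was sorted replicate 3. The median of the 4 was -0.15 log2 (set test adjusted p = 0.0241, 0.181 with an estimated correlation, 0.0553 with the spike-in block, 0.221 and 0.0529 with the filters at the median and the lower quartile, and 0.111 without sorted replicate 1). After centring on them it was 0.05 (set test adjusted p = 0.158).

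Among probe sets unnamed here, 247655_at (6.35 log2, SE 0.30, adjusted p = 0.00274) and 250781_at (5.89 log2, SE 0.66, adjusted p = 0.0125) had the largest rises, and 263689_at (-5.46 log2, SE 0.19, adjusted p = 0.00162) and 264775_at (-5.22 log2, SE 0.40, adjusted p = 0.00574) the largest falls, by the same rule as for the named genes but without a symbol. In the sorted cells 263689_at was near the floor (2.61).

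The 3 prime minus 5 prime levels of the control transcripts overlapped between the groups for actin and GAPDH and were higher in all sorted arrays for ubiquitin. The difference between the ends was 4.90 ± 0.16 log2 in the sorted cells and 5.12 ± 0.16 in the meristems for actin (SD, n = 3 each; exact permutation p = 0.3), 1.12 ± 0.03 and 1.07 ± 0.08 for GAPDH (exact permutation p = 0.5) and 1.15 ± 0.06 and 0.88 ± 0.10 for ubiquitin (exact permutation p = 0.1, the smallest this design allows). Adjusted over the 3 transcripts, the exact permutation p was 0.45, 0.5 and 0.3.

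**Figure D4:**
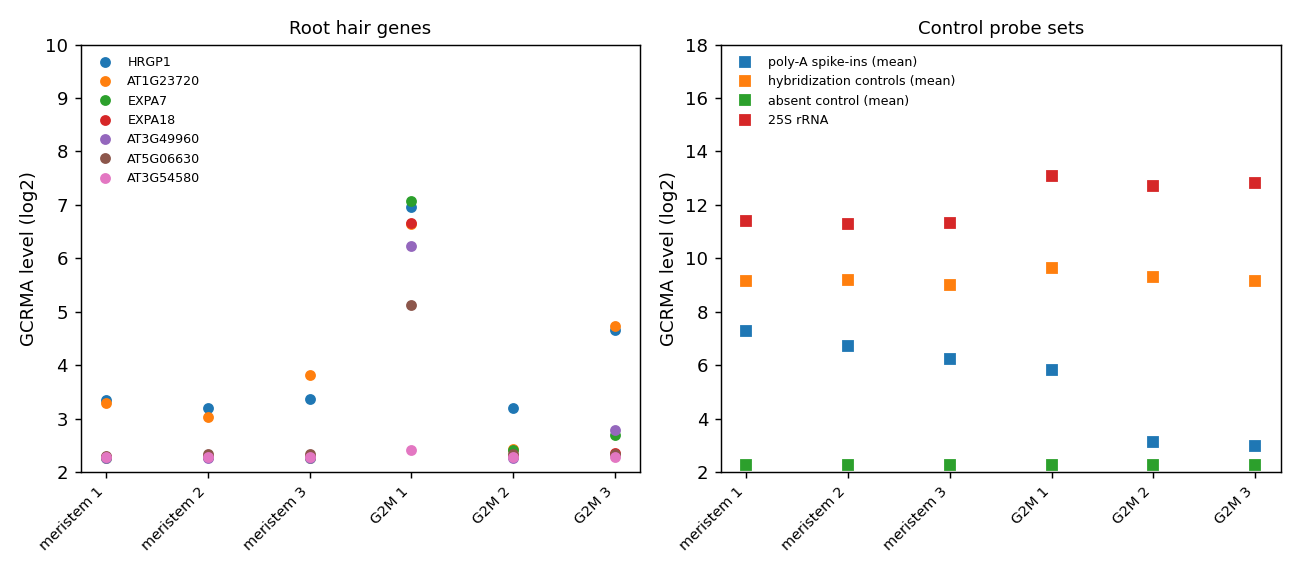
GCRMA level (log2, vertical) per array (horizontal) of 7 root hair genes (left) and of control probe sets (right), where squares for spike-ins, hybridization controls and the absent control are means over their probe sets. EXPA7 stands at 7.07 in sorted replicate 1 (G2M 1) and at 2.42 in sorted replicate 2, and the poly-A spike-ins are low in sorted replicates 2 and 3.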

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

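All tests in this part were chosen after the results were seen. Signals stood out in control probe sets that take no part in the comparison of the groups. The poly-A spike-in probe sets had mean levels of 5.81 in sorted replicate 1 and 7.26, 6.72 and 6.24 in meristem replicates 1, 2 and 3, against 2.28 for the absent control, while sorted replicates 2 and 3 had 3.13 and 2.97. Every sorted array thus lay below every meristem array, with a mean difference of -2.77 log2 (exact permutation p = 0.1, the smallest possible). The hybridization controls, added at a later step, were alike, at 9.37 ± 0.24 in the sorted cells and 9.11 ± 0.10 in the meristems (SD, n = 3 each). The 25S rRNA control probe set was higher in the sorted cells, at 12.87 ± 0.21 against 11.34 ± 0.06, a difference of 1.54 log2 (exact permutation p = 0.1, the smallest possible).

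The array of sorted replicate 1 differs from the other sorted arrays in both the spike-ins and the root hair genes. Of 7 root hair genes, a list fixed before the group differences were computed, 6 were detected there, at a median of 3.81 log2 above the meristems, against 0.00333 and 0.46 in sorted replicates 2 and 3. A wrong label is argued against by the 19 measured genes of the planned mitotic lists, which stood a median of 1.24 log2 above the meristems in this array (quartiles 0.59 and 2.02). A preparation difference marked by the spike-ins, if there was one, stays open, since this is the only 1 of the sorted arrays that carries them and the meristems hold few root hair cells. Cells of the differentiation zone may have passed the reporter gate, which should exclude them: such cells would dilute the target cells, and all 30 of the 30 called G2/M genes were lower in replicate 1 than in replicate 2, by a median of 1.47-fold. These genes were picked by their calls and are not independent of each other. Their median above the meristems was also lower in replicate 3 (2.42) than in replicate 2 (2.60). The count therefore does not show what lowered them. No group of the design isolates cells of the differentiation zone, and beyond this count no biological explanation was tested.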

How the results depend on the processing

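The spike-in block was chosen after the data were seen, the other alternatives with the design. The 2614 calls became 1249 with a trended robust prior (516 higher, 733 lower), 14927 with centring on the reference genes (12986 higher), 9114 with array weights (5023 higher, 4091 lower) and 235 with the replicate block (79 higher, 156 lower; 209 shared with the 2614). Higher calls numbered 1645 with the filter at the median and 1631 with the spike-in block. Centring on the reference genes adds the same shift to probe sets at the floor, which then differ between the groups with almost no spread; the cause of the array-weight count was not tested. At an adjusted p under 0.01 the count was 811, with a 2-fold minimum 1320, and with limma's treat at 1 log2 298. With 1 array left out it ranged from 959 to 3383, with 323 to 1752 higher and 636 to 1631 lower.

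With the replicate block, which leaves fewer residual degrees of freedom, members called fell to 0 mitotic regulators, 0 spindle genes, 0 kinesins, 1 further G2/M gene, 1 H2B gene, 0 further replication genes, 2 heat shock genes and 2 rapid stress genes; it changed no set test call. Rapid stress genes called were 19 with centring on the reference genes and 13 with array weights, and replication genes called were 6 with array weights. With 1 array left out, 3 to 7 mitotic regulators and 5 to 10 rapid stress genes were called. Camera called 15 of the 18 lists, 0 with an estimated correlation. Fry also called 15, with expansins and peroxidases in place of cytosolic ribosomal proteins and plastid-encoded genes. Centring on the reference genes shifts all genes alike, and this shift moved LBD29 from 0 to 0.193 and turned RPL28A (0.163), SMR2 (0.159) and CDC27a (0.0892) positive; none of these was called in the main setting.

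Of 67 named genes called, 10 kept the call in all 17 refits: STZ, CML38, XTH16, Prx37, SBT4.12, HTB4, PEP, HSP17.6C, AT4G26660 and AT4G29780. A further 27 lost it under the replicate block alone, and that block ended 56 calls in all. The trended prior ended 13, the spike-in block 16, and leaving out sorted replicates 1, 2 and 3 ended 7, 13 and 24; each meristem array left out ended 27. The number of arrays and the floor of the table limit what can be called.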

Other observations

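Apart from the planned fit, which gave the adjusted p-values and the calls, all tests in this part were chosen after the results were seen. Genes that carry only a locus code were among the largest changes, and those given here were picked after their values were seen. AT5G15950, an S-adenosylmethionine decarboxylase of polyamine synthesis, rose by 4.797 log2 (SE 0.14, adjusted p = 0.00111), and AT1G76640, next to CML38 by locus code, by 4.89 (SE 0.48, adjusted p = 0.00967). AT3G19430 fell by 6.03 log2 (SE 0.78, adjusted p = 0.0176), from 10.15 to 4.123. Jacalin-related lectin genes with consecutive locus codes fell together: AT1G52050 (-5.14 log2, SE 0.74, adjusted p = 0.0227), AT1G52060 (-4.96 log2, SE 0.67, adjusted p = 0.0195) and AT1G52070 (-4.997 log2, SE 0.87, adjusted p = 0.0355). Whether these locus-code genes keep their calls in other settings is not given here. With the replicate block 209 of all 2614 calls were kept.

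The sorted arrays also differed among themselves, in values that carry no test. The largest excess of sorted replicate 1 over replicate 2 among named genes was that of AT5G44020 (11.6 against 6.02). Peroxidase genes, picked after their values were seen, were among the 25 largest. Whether peroxidases were more frequent there than other genes was not tested. The fixed list of 6 class III peroxidases had a median of 0 log2 from the meristem mean in each sorted array. Of these 6, 3 stood at the floor on all arrays, which largely fixes that median, so it says little about peroxidases in general. AT5G17820 stood at 10.8, 5.29 and 8.00 in sorted replicates 1, 2 and 3, against 4.11, 3.67 and 4.69 in the meristems. AT3G01190 stood at 11.4, 6.05 and 9.88, against 8.62, 7.73 and 8.64, and AT4G30170 at 10.8, 5.82 and 9.52, against 10.9, 10.4 and 10.6. Of the expressed probe sets, 606 were higher in replicate 1 than in replicate 2 by over 1.5 log2 and 7 were lower by as much.

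The count of 2614 calls was set against the other splits of the 6 arrays into 3 and 3. Of 10 splits 1, the real one, gave as many, and the highest of the others gave 0; of the 4 splits that part all 3 replicate numbers, the others also gave at most 0. With 10 splits the share cannot fall under 0.1, too few for a share under 0.05. Every other split also mixes sorted and meristem arrays, so the difference between the groups enters its spread and lowers its calls. The count of 0 there is thus no measure of calls that arise without a group difference.

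The stress genes that were higher in the sorted cells form a pattern that the design ties to handling. Of 32 measured genes in the stress, wound and heat shock lists, 16 were called higher, with a median of 3.18 log2. Over all 9 heat shock genes, called or not, the medians in sorted replicates 1, 2 and 3 were 2.78, 2.98 and 2.90 log2 above the meristems. The root hair genes stood at 0.00333 and 0.46 in replicates 2 and 3 (upper quartiles 0.02 and 1.14). For the heat shock genes this argues against root hair cells in the sort as the whole cause. Over all 23 rapid stress and wound genes the medians were 1.39, 0.75 and 0.81, highest in replicate 1. In replicate 3 that median lay under the upper quartile of the root hair genes, so the comparison does not decide for them. The 16 genes stood a median of 3.06 and 3.15 log2 above the meristems in replicates 2 and 3 (lower quartiles 2.28 and 2.14). They were picked by their calls, which favour genes high in all sorted arrays, so they cannot decide either. A preparation difference stays open: 14 of the 16 stayed called with the spike-in split as a block (median 3.12), but that block rests on 1 sorted array, and protoplasting and sorting or the G2/M phase could each account for all 16, on the same 3 arrays.

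Sorted replicate 3 lay between replicates 1 and 2, in 95.2% of the 1115 expressed probe sets that differed between those by over 1 log2. A pool of the RNAs of replicates 1 and 2 stays open: with the share of replicate 1 that best matched 180 abundant probe sets (0.326), 7.26% of 606 probe sets lay over 1 log2 from the pool, too many for a close match and too few to exclude it. Among the 6 detected root hair genes 4 lay over 1 log2 under that pool. These 4 stood between 2.34 and 2.78 in replicate 3, near the floor, while the pool predicted levels between 3.89 and 5.57. The other detected ones, HRGP1 and AT1G23720, differed from the pool by -0.896 and -0.446 log2. A share of non-target cells that differs between the sorts may also place replicate 3 in the middle. Of the 30 called G2/M genes, 28 had a level in replicate 3 between those in replicates 1 and 2. A pool predicts this too, and most differing probe sets lay there, so the count does not tell these explanations apart. For non-target cells of a fixed mix, differing shares predict the same levels as a pool. The low root hair genes then bear equally on both. Over the expressed probe sets, replicate 3 differed from replicates 1 and 2 with an SD of 0.448 and 0.505 log2, against 0.835 between those. These values imply an own variance of -0.12 for replicate 3, which 3 independently varying samples would not give. A pool or a differing share of non-target cells could each give it. Under a pool the sorted arrays would hold fewer than 3 independent samples, while the labels name 3 biological replicates.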
